A study of Homo sapiens with 5 samples.

How the data were processed

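Open chromatin was mapped by DNase-seq, which sequences the ends left where the enzyme DNase I opens accessible DNA, in 3 kinds of human epithelial cell. Caco2 is a colorectal adenocarcinoma line that resembles intestinal epithelium, HBE are primary bronchial epithelial cells, and the epididymis cells are primary cells from adult tissue. The labels give 2 samples for Caco2, 1 for HBE and 2 for epididymis, and samples were grouped by cell type from these labels. The files held 3 peak lists, 1 per cell type, and the Caco2 and epididymis lists are named as combined. Whether tags or separate peak calls were combined is not given in the sources used here.

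Each peak carries a position and a score, and the deposited score is a whole number. Per the file headers, which only the HBE list has, the peaks were called by HOMER's findPeaks program in its DNase mode, with a peak size of 150 bp, a minimum distance of 300 bp between peaks, a false discovery rate of 0.001 (20 tags), at least 4-fold over the surrounding 10 kb and a local Poisson p of 0.0001. The same header names a tag directory labelled as replicate 3 of NHBE, while the labels used here give 1 HBE sample, so which culture the list came from was not settled. Per the file headers, HBE tags were normalized to a total of 10000000, so a score of 1 stood for 8.34 tags and the tag threshold for a score of 2.40. The HBE scores multiplied by that factor summed to 9475223 tags, which was 100.6% of the 9423367 tags that the header counts in peaks, so the score was read as the authors' normalized tag count, rounded. For Caco2 and epididymis the same meaning was inferred from the values and not stated by a header. Bowtie 1.0.0, HOMER and the build hg19 are named, without a role, per the submitters' processing notes. Peaks reached position 249240560 on chromosome 1, beyond the end of that chromosome in GRCh38, which excludes that build. Scores were used only to rank and describe peaks within their own list.

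Depth was known for HBE alone, where the header gives 83405716 tags with 11.3% in peaks. The depth behind the Caco2 and epididymis lists is not given in the sources used here. With 1 list per cell type and no values per replicate, no spread between replicates could be computed and no test between cell types was run. Shares carry Wilson 95% intervals, which cover counting error only and treat peaks as independent.

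Peaks on chromosome Y and the mitochondrial genome were left out. Overlap meant at least 1 shared bp. Chance overlap came from 1000 circular shifts of a list along each chromosome, and, added after the lists had been seen, from 1000 local shifts of 5 to 50 kb, which keep the regional density of peaks. Peaks of the 3 lists that touched or overlapped were merged into regions, and each region was assigned to the lists it held. Windows of 100 kb were counted from position 1 of each chromosome. The procedure was tested on simulated lists, where all 7 classes of merged region were recovered exactly over 226288 simulated regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

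Regions were named by a rule set before the data were examined: every peak within 100 kb of CFTR, the 5 windows per cell type with the most regions found in that list alone, and the 3 highest-scoring peaks per list among those found in that list alone. No hg19 genome or annotation was used here. The gene table at hand describes GRCh38.p14, so none of its coordinates were used. The planned shares of peaks at promoters, exons and introns, the percentiles of gene lists and the motif shares were therefore not run, and the plan was to name regions by position alone. In a departure from that plan, CFTR itself was placed from general knowledge of hg19, and its length so placed differed by 62 bp from the table's. Start sites of marker genes from the lists set beforehand were placed in the same way and appear only among the additional observations. The values of a single marker gene are not reported here, although it is counted in its list. Alternatives tried were a larger overlap, peaks of 150 bp, the upper 50% of each list by score, lists of equal length by score or, for merged regions, by random thinning, autosomes alone, wider merging and other windows. Added after the data had been seen were random thinning for the pair overlaps, peak centres within 500 bp and removal of the highest 0.1% of scores.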

Results

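DNase-seq peaks marked open chromatin in Caco2 colorectal adenocarcinoma cells (2 samples in 1 combined list), primary bronchial epithelial cells (HBE, 1 sample) and primary epididymis cells (2 samples in 1 combined list). The series concerns cis-regulatory elements and chromatin structure at CFTR, the chloride channel gene mutated in cystic fibrosis, so the lists were compared genome-wide and at that gene. Caco2 had 75037 peaks, HBE 127946 and epididymis 128305, all of the same width, covering 11.3, 19.3 and 19.4 Mb. The Caco2 list was thus 0.586 times as long as the HBE list. The median authors' score was 8 in Caco2, 5 in HBE and 9 in epididymis, with maxima of 387, 2007 and 700. Peaks with a score of 3 or less made up 10.6% of the Caco2 list, 29.8% of the HBE list and 5.96% of the epididymis list. No replicate spread was measurable for any value here, since each cell type had a single list.

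The comparison of whole lists asked how much open chromatin the cell types shared. Of the Caco2 peaks, 51.8% (Wilson 95% interval 51.4 to 52.1) overlapped an HBE peak and 60.0% (59.6 to 60.3) an epididymis peak. Of the HBE peaks, 52.8% (52.5 to 53.0) overlapped an epididymis peak and 30.4% (30.1 to 30.6) a Caco2 peak. Epididymis peaks overlapped HBE peaks in 52.6% (52.3 to 52.9) and Caco2 peaks in 35.1% (34.8 to 35.3) of cases. These shares were 23.6 to 27.9 times those from local shifts, which gave 2.19% for Caco2 in HBE, 2.15% for Caco2 in epididymis and 1.99% for HBE in epididymis. With equal numbers of top-scoring peaks per list, HBE in epididymis came highest at 51.7%, before Caco2 in epididymis (47.9%) and Caco2 in HBE (40.4%). That setting keeps the whole Caco2 list and drops only weaker HBE and epididymis peaks. Lists thinned at random to equal length gave 30.9%, 35.1% and 30.4%. Thinning lowers these shares by nearly the same factor, so the kept order of the full lists carries no information.

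**Figure D1:**
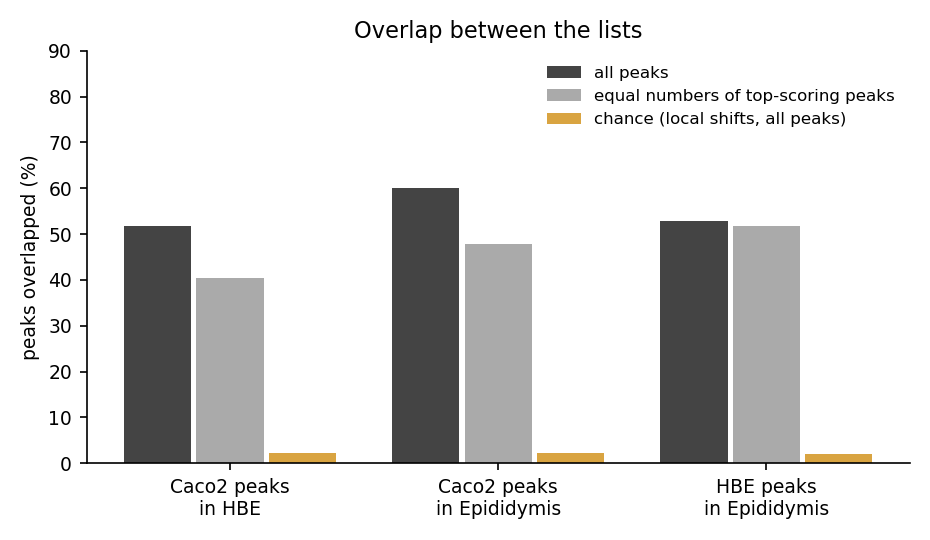
Percent of the peaks of one list that overlap a peak of another (vertical axis) for 3 pairs of lists, with all peaks (dark bars), with equal numbers of top-scoring peaks (grey bars) and as the mean of local shifts (yellow bars). Caco2 in epididymis is highest with all peaks (60.0%), and HBE in epididymis is highest with equal lists (51.7%), where the Caco2 list is whole and the others lose their weaker peaks.

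Merging the lists gave 213742 open regions. All 3 cell types shared 34438 of them (16.1%). HBE and epididymis alone shared 33314 regions (15.6%), which was 3.10 times the 10747 of Caco2 and epididymis and 7.23 times the 4608 of Caco2 and HBE. HBE had 55586 regions found in no other list, epididymis 49805 and Caco2 25244. These amounted to 43.4% (43.2 to 43.7) of the regions with an HBE peak, 38.8% (38.6 to 39.1) of those with an epididymis peak and 33.6% (33.3 to 34.0) of those with a Caco2 peak. These orders depended on how lists were made equal, and neither way treats the lists alike. Equal lists of top-scoring peaks left Caco2 whole. The lowest score kept was 4 in HBE and 7 in epididymis, with ties broken at random. There Caco2 had the most regions to itself (33741, against 30786 in HBE and 25207 in epididymis). HBE and epididymis alone shared 13785, against 10830 for Caco2 and epididymis and 5252 for Caco2 and HBE. In lists thinned at random, which also leave Caco2 whole, HBE had the most to itself (40744, against 37616 in Caco2 and 37223 in epididymis), while HBE and epididymis alone shared 11401, fewer than the 14529 of Caco2 and epididymis and close to the 11009 of Caco2 and HBE.

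**Figure D2:**
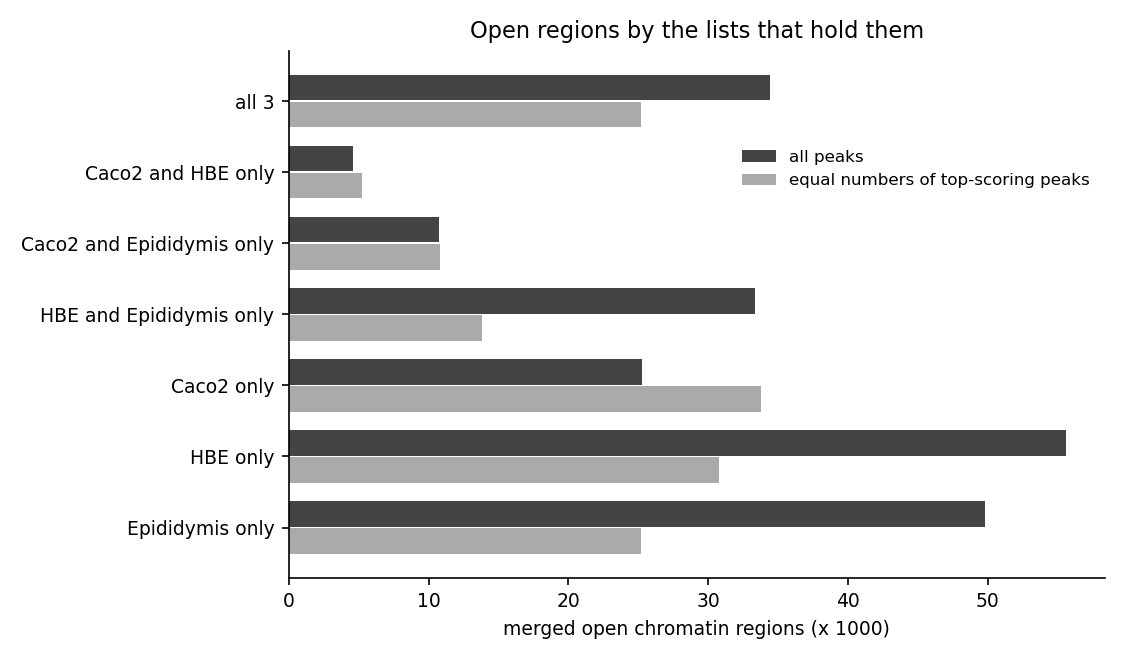
Number of merged open regions (horizontal axis, in units of 1000) in each combination of lists, with all peaks (dark bars) and with equal numbers of top-scoring peaks (grey bars). With all peaks HBE has the most regions to itself (55586), and with equal lists, where the Caco2 list is whole and the others lose their weaker peaks, Caco2 does (33741).

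Peaks shared by all cell types were the stronger ones within each list. In Caco2 the median score was 13 for peaks in regions of all 3 lists and 6 for peaks of Caco2 alone. The same medians were 8 and 4 in HBE and 16 and 6 in epididymis. Among the highest-scoring 20% of peaks, 9.38% of Caco2, 20.3% of HBE and 9.21% of epididymis peaks lay in their own list alone. Among the lowest-scoring 20%, these shares were 53.8%, 63.6% and 62.7%. Over the 34438 regions in all lists, scores ranked alike, with Spearman's rho across regions of 0.687 for Caco2 and HBE, 0.635 for Caco2 and epididymis and 0.532 for HBE and epididymis. Regions are not independent replicates, so no p-value is given.

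**Figure D3:**
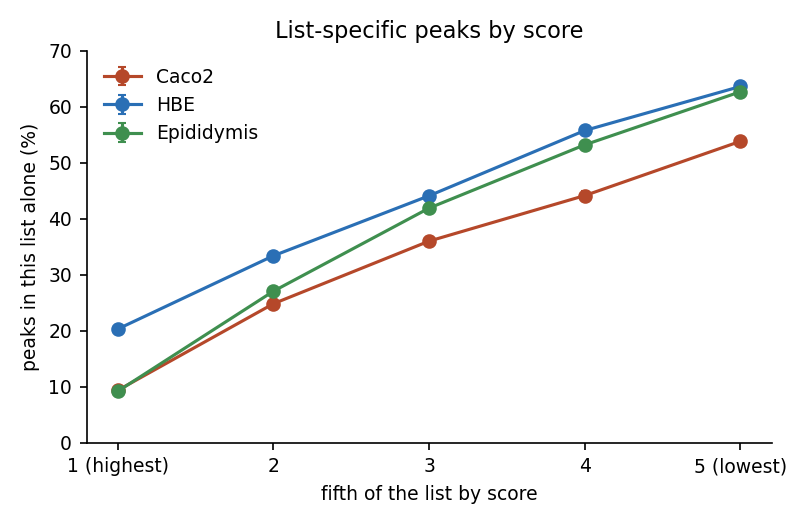
Percent of a list's peaks found in that list alone (vertical axis) by 20% groups of the list ranked by score (horizontal axis, highest at left), for Caco2, HBE and epididymis, with Wilson 95% intervals that are about as small as the points. The share rises from left to right in each list, from 9.38% to 53.8% in Caco2.

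At CFTR, on chromosome 7, the question was which candidate regulatory elements were open in which cell type. The gene and 100 kb on either side held 14 Caco2, 16 HBE and 20 epididymis peaks. Random windows of the same length had medians of 8, 16 and 16, so the counts stood at the 70.2, 50.4 and 60.8 percentiles of 10000 such windows. These peaks formed 34 regions, of which 2 were open in all cell types, 7 in HBE and epididymis alone, 3 in Caco2 and epididymis alone, and 2 in Caco2 and HBE alone. Caco2 had 7 regions to itself, HBE 5 and epididymis 8. Because the gene was placed from general knowledge of hg19, distances from its start and end are approximate, while peak positions are those of the files. Whether flanking peaks lie inside a neighbouring gene was not examined.

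The CFTR promoter region was open in every list. The Caco2 peak (117119908 to 117120058) had a score of 13, at the 65.9 percentile of its list, and the epididymis peak (117119726 to 117119876) a score of 14, at the 73.8 percentile. The HBE peak (117119768 to 117119918) had a score of 2, at the 3.73 percentile. The Caco2 and epididymis peaks did not overlap each other and were merged only through this weak HBE peak. The other region common to all lists lay 47.3 kb beyond the gene end, on the side of CTTNBP2, at 117355971 to 117356121 in Caco2, with scores of 9 in Caco2, 4 in HBE and 9 in epididymis.

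Upstream of CFTR, HBE and epididymis shared a pair of peaks that Caco2 lacked. The farther one, 44.3 kb before the gene, had a score of 12 in HBE (117075663 to 117075813, 82.3 percentile) and 12 in epididymis (117075711 to 117075861, 67.2 percentile). The nearer one, 34.6 kb before the gene, had a score of 7 in HBE (117085331 to 117085481, 66.0 percentile) and 12 in epididymis (117085400 to 117085550, 67.2 percentile). Caco2 had no peak over the 77.4 kb that hold both. Some 80 kb before the gene, toward ASZ1, Caco2 (117040005 to 117040155) and HBE (117039994 to 117040144) shared a peak with a score of 3 in each. Epididymis alone had peaks with a score of 11 at 117042337 to 117042487 and at 117110831 to 117110981. Caco2 and epididymis shared peaks at 117041504 to 117041654 and at 117118930 to 117119080 in Caco2, with scores of 4 and 6 at the former and 4 and 5 at the latter. Caco2 alone had a peak with a score of 3 at 117033934 to 117034084.

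Inside CFTR, each cell type showed a different set of open sites. Caco2 alone had a peak 10.2 kb into the gene (117130112 to 117130262), in the first intron, where an intestinal enhancer is known, with a score of 5 at the 26.1 percentile. Caco2 alone also had weaker peaks at 117172879 to 117173029, 117245812 to 117245962 and 117305538 to 117305688, with scores of 3, 4 and 3. Epididymis alone had peaks at 117121176 to 117121326 and 117294848 to 117294998, with scores of 5 and 7. HBE had no peak over 102.8 kb from the promoter into the gene, and epididymis none over 107.4 kb. Caco2 and HBE shared a peak 102.6 kb from the start, with scores of 4 and 8 (117222586 to 117222736 in HBE). HBE alone had peaks at 117241112 to 117241262, 117252828 to 117252978 and 117280602 to 117280752, with scores of 7, 4 and 2. HBE and epididymis shared a peak at 117228567 to 117228717 in HBE, with scores of 3 and 4. Near the gene end, HBE and epididymis shared a peak at 117306264 to 117306414 in HBE, with scores of 5 and 8.

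Beyond the gene end, 14.6 kb away, Caco2 (117323256 to 117323406, score 5) and epididymis (117323268 to 117323418, score 14) overlapped, and a separate HBE peak (117323083 to 117323233, score 4) lay within 500 bp. Epididymis alone had a peak with a score of 13 at 117357113 to 117357263, and weaker ones at 117346365 to 117346515, 117369004 to 117369154 and 117371519 to 117371669, with scores of 4, 8 and 4. HBE and epididymis shared peaks at 117313623 to 117313773, 117328354 to 117328504 and 117390769 to 117390919 in HBE, where the HBE scores were 3, 6 and 2 and the epididymis scores 7, 4 and 4. Caco2 alone had peaks with a score of 3 at 117314030 to 117314180, which lay within 500 bp of the HBE and epididymis peaks just named, and at 117329486 to 117329636. HBE alone had a peak with a score of 4 at 117344316 to 117344466. Many peaks in the window were weak: in the upper 50% of each list by score, 2 Caco2, 6 HBE and 8 epididymis peaks remained. The absence of a peak is therefore a statement about the list and its depth, not about the DNA.

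**Figure D4:**
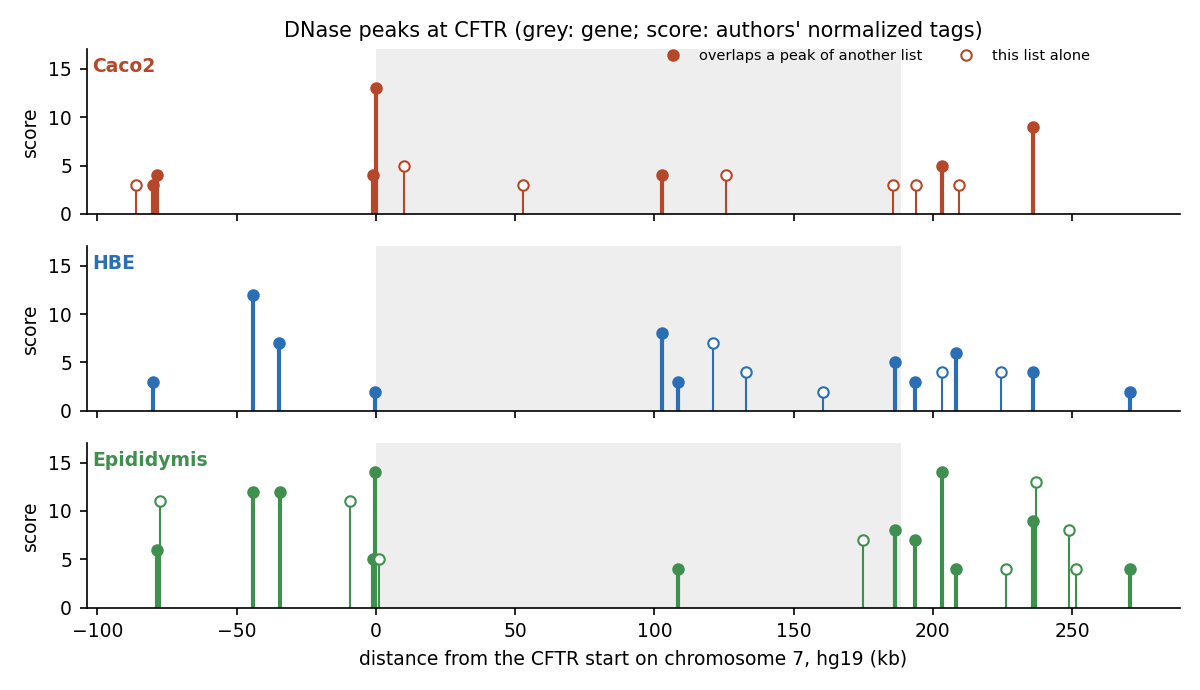
Authors' score (vertical axis, normalized tags) of each DNase peak against its distance in kb from the CFTR start on chromosome 7, hg19 (horizontal axis), for Caco2, HBE and epididymis. Filled points overlap a peak of another list, open points are found in 1 list alone, and the grey band is the gene. The peaks 44.3 and 34.6 kb upstream appear in HBE and epididymis and not in Caco2.

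Peaks fell unevenly on some autosomes in Caco2. Chromosome 4 held 2.95% of Caco2 autosomal peaks, 5.10% of HBE and 5.13% of epididymis peaks. On chromosome 8 the shares were 3.12%, 4.71% and 4.92%. Caco2 had the larger share on chromosome 11, with 6.35% against 5.17% in each of the others, and on chromosome 19, with 4.68% against 3.13% in epididymis, and 1.34 times the HBE share. These chromosomes are examples. Caco2 shares were also 1.21, 1.25, 1.24 and 1.24 times those of HBE on chromosomes 16, 17, 20 and 22, and 0.798 and 0.775 times on chromosomes 9 and 18. Copy number of this cancer line can move such shares and was not examined. In equal lists of top-scoring peaks the chromosome 4 share of Caco2 was 0.687 times that of HBE, and the chromosome 19 share was 1.03 times that of HBE. On chromosomes 16, 17, 20 and 22 the ratios to HBE were then 1.06, 1.05, 1.18 and 0.988. On chromosomes 9 and 18 they were 0.794 and 0.835. The Caco2 excess over HBE on chromosomes 16, 17, 19 and 22 was thus small or absent in that setting. In the upper 50% of each list, chromosome 4 held 1.85% of Caco2, 4.03% of HBE and 4.41% of epididymis peaks, and chromosome 19 held 6.84% of Caco2, 4.95% of HBE and 4.07% of epididymis peaks.

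The 100 kb windows with the most regions of 1 list alone were located, with no test of clustering. In Caco2 the 5 windows named began at 17000001 on chromosome 1 (13 regions of Caco2 alone), 19600001 on chromosome 18 (11), and at 20300001 on chromosome 2, 17500001 on chromosome 11 and 28500001 on chromosome 13 (10 each). In HBE they began at 132600001 on chromosome 4 and 91700001 on chromosome 14 (13 each), and at 40400001 on chromosome 1, 152900001 on chromosome 1 and 11200001 on chromosome 3 (12 each). The window at 152900001 on chromosome 1 held no region of any other class. In epididymis they began at 206500001 on chromosome 1 and 51900001 on chromosome 6 (13 each), 244200001 on chromosome 1 and 56200001 on chromosome 18 (12 each), and 48500001 on chromosome 1 (11). Over the 26342 windows with any region, the median was 0 for Caco2, 2 for HBE and 1 for epididymis, and the 99th percentile was 6, 8 and 8. The last windows named were taken from ties by chromosome order: 3 of 8 windows with 10 regions in Caco2, 3 of 9 with 12 in HBE and 1 of 6 with 11 in epididymis.

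The highest-scoring peaks of a single list were also located. In Caco2 they were on chromosome 17 (26698545 to 26698695, score 175), chromosome 20 (62169445 to 62169595, score 144) and chromosome 2 (3522851 to 3523001, score 140). In HBE they were on chromosome 21 (9826735 to 9826885, score 1206), chromosome 16 (33961252 to 33961402, score 442) and chromosome X (125715170 to 125715320, score 218). In epididymis they were on chromosome 1 (121485114 to 121485264, score 395), chromosome 16 (33956444 to 33956594, score 105) and chromosome 2 (133022653 to 133022803, score 88). Several of these had a peak of another list nearby, centre to centre: at 296 bp for the Caco2 peak on chromosome 20, 184 bp for that on chromosome 2, 433 bp for the HBE peak on chromosome 21 and 322 bp for the epididymis peak on chromosome 1. Without an hg19 genome or annotation, whether any of them lies in a repeat was not examined. They are therefore not read as cell type specific open sites.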

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

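Every value here comes from 1 list per cell type, so leaving out replicates was not possible. No paired analysis was possible because the lists are per cell type and hold no values per replicate. Some orders turned: in equal top-scoring lists HBE in epididymis became the highest overlap and Caco2 alone (33741) passed HBE alone, and under random thinning Caco2 and epididymis (14529) passed HBE and epididymis. Random thinning of pair overlaps, centres within 500 bp and removal of the highest 0.1% of scores were chosen after the data had been seen; the other settings below were planned. For Caco2 in HBE, Caco2 in epididymis and HBE in epididymis, overlap of at least 76 bp gave 47.7%, 56.2% and 48.5%, the upper 50% of each list gave 57.6%, 64.3% and 51.5%, equal top-scoring lists 40.4%, 47.9% and 51.7%, random thinning 30.4%, 35.1% and 30.9%, and centres within 500 bp 56.5%, 63.8% and 57.4%. Both ways of equal length shortened HBE and epididymis but not Caco2. Thinning thereby lowered the HBE and epididymis count, and top-scoring lists raised Caco2 alone, by construction. In the upper 50% of each list, 18927 regions were in all lists, 2793 in Caco2 and HBE, 5296 in Caco2 and epididymis, 14181 in HBE and epididymis, 10502 in Caco2 alone, 28072 in HBE alone and 25747 in epididymis alone, fewer because fewer peaks entered. Equal top-scoring lists gave 13785 for HBE and epididymis, 30786 for HBE alone and 25207 for epididymis alone. Random thinning gave 11883 for all lists, 11009 for Caco2 and HBE and 11401 for HBE and epididymis. Of 42 alternative region counts, 29 stayed within 1.5 times. At CFTR the upper 50% left 2 Caco2, 6 HBE and 8 epididymis peaks, and flanks of 200 kb raised HBE to 27 and epididymis to 31. The 6 alternative score medians did not move, all 12 alternative chromosome shares left their intervals, and 4 of 6 window maxima moved by over 1.5 times with 50 or 250 kb windows. The cause was not tested except where stated. Promoter, gene list and motif alternatives were not run. Depth is known for HBE alone, so what it limits was not tested.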

Other observations

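Start sites of intestinal marker genes had peaks most often in Caco2 and those of epididymis genes most often in epididymis. This comparison was not planned, and gene positions came from general knowledge of hg19 rather than from an annotation, written down after the windows above had been seen. Of the 199 genes in the marker lists, 83 were not placed. Of the 116 placed, 75 had the chromosome and a length within 1% of the gene table and were used. A wider tolerance of 20% was tried because well-known markers had dropped out, kept 110 genes and is given as the alternative; the narrower tolerance, written first, was taken as the main one after both results had been seen. The genes used were 11 of 20 housekeeping, 12 of 25 intestinal, 11 of 30 epididymis, 10 of 20 basal, 9 of 24 general epithelial, 7 of 20 mesenchymal, 4 of 12 endothelial, 7 of 16 immune, 3 of 20 airway and 1 of 12 CFTR neighbourhood genes (CFTR itself), so the counts do not describe whole lists. The 11 housekeeping genes used, such as ACTB and POLR2A, had a peak within 1 kb of the start in every list, while random positions had one in 4.39% of cases in Caco2, 7.73% in HBE and 7.74% in epididymis. Of the 12 intestinal genes, 8 had a start peak in Caco2, 1 in HBE and 4 in epididymis. APOA1, an apolipoprotein, ALPI, the intestinal alkaline phosphatase, FABP1, a fatty acid binding protein, ISX, an intestinal homeobox factor, and GUCY2C, an intestinal guanylate cyclase, had one in Caco2 alone, with scores of 39, 34, 13, 18 and 5. KRT20 went the other way, with one in epididymis alone (score 3), while CDX1, APOA4 and GPA33 had none in any list. At the wider tolerance, 13 of 19 intestinal genes had a start peak in Caco2, 1 in HBE and 8 in epididymis.

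Of the 11 epididymis genes, 9 had a start peak in epididymis, 6 in Caco2 and 3 in HBE, and 12, 7 and 3 of 15 at the wider tolerance. PAX8, HOXA9, HOXA11 and HOXD9, developmental transcription factors, had one in epididymis alone, with scores of 19, 10, 9 and 14. WFDC2 went the other way, with one in Caco2 (score 11) and HBE (score 3) and none in epididymis. AQP9 had none in any list. Of 10 basal epithelial genes, 8 had a start peak in HBE and 6 in each of the other lists, and at the wider tolerance 12 of 17 in HBE, 9 in Caco2 and 10 in epididymis. COL17A1, DSG3 and SERPINB5 had one in HBE alone, with scores of 3, 3 and 6, while KRT14 had none in any list. NGFR went the other way, with one in Caco2 (score 83) and epididymis (score 14) and none in HBE. General epithelial genes were open widely, at 7 of 9 starts in Caco2 and 8 of 9 in HBE and in epididymis. Of 7 mesenchymal genes, 2, 3 and 4 had a start peak in Caco2, HBE and epididymis. Endothelial genes had 0, 2 and 2 of 4, immune genes 2 of 7 in each list, and airway secretory or ciliated genes 1, 2 and 2 of 3. The lists are small and no test was run on them.

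A few of the 15 windows named were set against genes picked by recognition after the windows were seen, with no rule and no search of the other windows. The Caco2 window on chromosome 11 overlapped USH1C, a brush border scaffold, and the Caco2 window on chromosome 18 ended 49.4 kb before GATA6, an endodermal transcription factor. The HBE window at 152900001 on chromosome 1 overlapped SPRR1A and SPRR3, which encode proteins of the cornified envelope. The epididymis window on chromosome 6 overlapped PKHD1, the gene of polycystic kidney and hepatic disease. The HBE window on chromosome 4 differed from the rest in its short span, with 13 peaks in 39.5 kb, and in its low maximum score of 5. Its median score of 4 did not set it apart, since the HBE window on chromosome 3 had a median of 3.5.

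Of the tests that follow, those of regional density as the source of the whole overlap, of weak HBE peaks and of shifted summits were chosen only after related values had been seen. HBE and epididymis alone shared 3.10 times as many regions as the next pair. Regional density of open chromatin, as kept by local shifts, does not account for the overlap itself, which was 26.4 times its local-shift level. The bound for this was set after the ratio of 0.948 given below was known, so the value stands as a description. The excess of this pair over the others stays open. Relative to local shifts, its overlap was 0.948 times the larger Caco2 value, which met the bound set for density alone. Its fold of 26.4 lay between those of Caco2 with epididymis (27.9) and Caco2 with HBE (23.6). Circular shifts, which do not keep regional density, gave the same order (39.4, 44.0 and 37.7), so the met bound cannot point to density. These folds also count regions in all 3 lists, whereas the 3.10 does not. Local shifts and the bound for density alone were chosen after the lists and region counts had been seen, but before the ratio of 0.948 was computed. A shorter Caco2 list may add to the pattern. For it, a ratio of at most 1.1 in equal top-scoring lists had been required before the ratio was computed, and the value was 1.27. The ratio was 0.785 after random thinning, but both settings leave Caco2 whole and shorten the others, so list length and cell type cannot be told apart. A kinship of the cell types is an untested biological alternative.

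HBE had the most regions to itself. Weak peaks near the calling threshold are a candidate explanation that the values leave open. For it, the share of HBE peaks found in HBE alone was 3.13 times as high in the lowest-scoring 20% as in the highest, above the bound chosen. The test chosen for weak peaks also required that HBE no longer have the most regions alone in equal top-scoring lists. That requirement was met too, with 30786 regions in HBE alone and 33741 in Caco2 alone, so the test as written was met. Meeting it does not decide for weak peaks, since these lists take weak peaks from HBE and none from Caco2. A comparison that was not part of the written test was also made. HBE had the largest share alone among its highest-scoring 20% too (20.3% against 9.38% and 9.21%). Those HBE peaks scored 11 or more, above the threshold of 2.40. The groups are ranks within a list, reaching down to 22 in Caco2 and 16 in epididymis, so they do not compare like strengths. The added comparison therefore does not decide against weak peaks. HBE was also highest in the lowest-scoring 20% (63.6% against 53.8% and 62.7%). The ratio of lowest to highest was larger in Caco2 (5.74) and epididymis (6.80). Their highest groups had small shares alone, so the ratio does not set HBE apart. Random thinning left HBE with the most (40744, against 37616 in Caco2 and 37223 in epididymis). It cannot bear on weak peaks, since it keeps their share of each list. Cell type differences remain open and untested.

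The strongest peaks of single lists often had a near neighbour in another list. Within 1 kb, 64% of the top 50 in Caco2, 72% in HBE and 82% in epididymis had one, against 21.6%, 19.1% and 20.3% of all peaks found in 1 list alone. A repeat or pile-up whose summit moved between lists may explain this. The ratio was 2.97 in the lowest list and 4.04 in the highest, and the bound chosen for it was 3 in every list, so the test did not decide. Strong open sites with neighbouring peaks are an untested alternative.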
